A study of Homo sapiens with 18 samples.

How the data were processed

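RNA from 6 lines of HEK human embryonic kidney cells was measured on 18 Affymetrix arrays, 3 per line. Per the labels, 3 lines were ATXN1L wild type (the parental cells and the CRISPR controls N4 and N8) and 3 were labelled ATXN1L-KO (A10, A30 and B21). RNA was extracted with the Qiagen miRNeasy kit. The deposited values are on the log2 scale, 1 per probe set and array, and were made by the authors with Affymetrix Expression Console, whose version and settings are not given in the sources used here. The scale was read from the values, which ran from 0.57 to 14.84. The array medians lay between 5.09 and 5.18, so the values were used as deposited, with no further normalisation and a pseudocount of 0. No detection flags were used, and the number of arrays limits the precision of each value.

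Of 53617 probe sets, 16098 had exactly 1 gene symbol, 0 had several and 37519 had none. The probe sets with a symbol covered 14884 genes. For the 779 genes with several probe sets, the one with the highest mean over all arrays was used. A gene was tested if at least 3 arrays exceeded 5.6, the 40th percentile of all values of named genes, which left 9686 genes. The current gene annotation served for names and for the order of neighbouring genes, and 22 list genes were renamed to their current symbols.

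The cell line was the unit of replication for genotype, since arrays of a line share its clonal history. KO-labelled and wild-type lines were compared on the means of 3 lines against 3 with limma 3.58.1 in R 4.3.3, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. With 3 lines against 3, an exact permutation test of a single value cannot go below a two-sided p of 0.1. Each KO-labelled line against the wild-type lines, and N4 and N8 against the parental cells, were compared on arrays with limma. These tests cover the spread between cultures of a line, not that between independently edited clones. Differences among the 3 KO-labelled lines and among the 3 wild-type lines were tested with limma's F test. All limma and list tests were two-sided. Errors of differences are limma standard errors.

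Before the data were examined, 20 gene lists were written from general knowledge, with the rule for naming genes and the comparisons. Lists were tested on the line means with camera at a preset correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. A list member counts as measured here if a probe set carried its symbol and the gene passed the filter. Other listed genes may still have probe sets on the array, without a symbol or too dim. Lists with fewer than 3 measured members were left out: the replication-dependent histone genes had 0 and the leukocyte markers 2, of 7 with a symbol. Genes named are ATXN1L, ATXN1 and CIC, the 5 with the smallest p in each direction for genotype since none passed, up to 4 members of each list with the smallest p, and the 5 largest rises, falls or ranges of the other comparisons. Genes named for the difference between replicates, for replicate 1 of A10, for cholesterol synthesis in N8 and as ends of runs were chosen after their values were seen. XIST and Y-linked genes were left out.

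Alternatives covered the filter, the normalisation, the choice of probe set, the variance model, the thresholds, the unit of replication, the control lines, a replicate-number term, and leaving out each array and line. After the data were examined, a difference between replicate 1 and replicates 2 and 3 led to fits within those parts and with that difference as a term. Neighbouring genes that shifted together led to centring each line on the running median of 41 neighbours, and N8 was also left out of the reference. Other splits of the lines or arrays, at most 100 for each comparison, were run in the same way. The fits were tested on simulated data with 200 changed genes in 9686. The genotype comparison recovered 94.3% of 2-fold and 99.7% of 4-fold changes, with 3.99% false among its calls. The simulated changes were equal in all 3 KO-labelled lines, with no replicate 1 difference and no shifts shared by neighbouring genes. These shares therefore need not hold for the real data, where PLXDC2 differed by −2.21 between the genotypes and did not pass (limma adjusted p = 0.172). Figures were drawn with Python's matplotlib 3.10.9, from tables read with pandas 2.3.3 and numpy 2.4.6.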

Results

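Gene expression was measured in 6 HEK lines, with 3 cultures and 3 arrays per line. HEK cells are an established human embryonic kidney line. The title of the series names CIC, a transcriptional repressor, and ATXN1L, a protein known to bind it, so the comparison asks how gene expression differs where ATXN1L was edited. Array medians ran from 5.09 to 5.18 (log2). Arrays of the same line correlated at r = 0.978 to 0.994 across genes and arrays of different lines at r = 0.957 to 0.990, where genes are not independent replicates. The first principal component held 27.3% of the variance and the second 14.95%. The median SD over genes was 0.12 between single arrays of a line (log2). Between line means, each over 3 arrays, it was 0.10 for the wild-type and 0.11 for the KO-labelled lines. Averaging lowers the array spread in a line mean, so these SDs do not show that lines differ less than cultures.

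Replicate 1 of the lines differed from replicates 2 and 3. With the line as a term, 829 genes were higher and 971 lower in replicate 1. EGR1, an early-response gene, was lower in replicate 1 by −1.10 ± 0.17 (SE), CCN2 by −0.98 ± 0.20 and ANKRD1 by −0.97 ± 0.22. DUSP5 and SPRY4, members of the CIC target list, were lower by −0.54 ± 0.12 and −0.54 ± 0.11. The microRNA genes MIRLET7F1 and MIR222 were higher by 1.03 ± 0.17 and 0.85 ± 0.13. Every replicate number is present in all 6 lines.

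Replicate 1 of A10 stood apart from its line. With the mean over all arrays removed, it correlated at r = 0.395 with replicate 1 of N4 and 0.377 with replicate 1 of the parental cells, but at 0.135 and 0.014 with the other A10 arrays. Replicate 1 of the parental cells and of N4 were also nearest to each other (r = 0.415), but correlated at 0.338 to 0.372 with their own lines. It is the low correlation with its own line that set replicate 1 of A10 apart. PLXDC2 was at 6.11 in replicate 1 of A10, 4.54 and 4.66 in the other A10 arrays and 7.72 in the wild-type lines. CADPS2 was at 6.66 against 4.73 and 4.96, with 6.81 in the wild-type lines. CHRDL1 (5.12 against 5.22 and 5.42, wild-type lines 6.86) and MOSPD1 (10.46 against 10.70 and 10.75, wild-type lines 9.44) were close to the other A10 arrays. Over the 32 genes that differed by at least 1 (log2) in A10 replicates 2 and 3, replicate 1 reached a median of 35.1% of that difference (quartiles 13.4% and 56.0%). In N4, N8, A30 and B21 the same medians were 89.3%, 93.8%, 91.4% and 88.1%.

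The ATXN1L signal was higher, not lower, in every KO-labelled line, at 7.41 ± 0.06 (SD, n = 3 lines) against 7.16 ± 0.05 in the wild-type lines. The difference of 0.25 ± 0.08 (SE) did not pass the test over all genes (adjusted p = 0.468). Against the wild-type lines, ATXN1L differed by 0.22 in A30 (adjusted p = 0.0160) and 0.32 in B21 (adjusted p = 0.00312), and by 0.20 in A10 (adjusted p = 0.0654), where replicate 1, at 7.20, lay within the wild-type arrays (7.05 to 7.29). The edited part of the gene is not given in the sources used here, so the probe set signal cannot check the genotype, and the lines are named by their labels. ATXN1, the related CIC partner, differed by 0.13 ± 0.11 (adjusted p = 0.717), and CIC itself by −0.06 ± 0.08 (adjusted p = 0.827).

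Between KO-labelled and wild-type lines, the smallest p among higher genes belonged to ETV5, a transcription factor gene repressed by CIC, at 5.98 ± 0.12 against 5.05 ± 0.15 (SD, n = 3 lines). Its difference was 0.93 ± 0.10 (SE, adjusted p = 0.0762), with all 9 wild-type arrays (4.62 to 5.54) below the filter value of 5.6, where background was not measured. EDIL3, which encodes a secreted adhesion protein, differed by 1.00 ± 0.14 (adjusted p = 0.0895), MIR4521 by 0.95 ± 0.16, MALT1 by 0.52 ± 0.10 and ETV1 by 0.60 ± 0.12. Lower were CADPS2, a vesicle exocytosis gene, by −1.36 ± 0.17 (adjusted p = 0.0762), and CHSY3, a chondroitin synthase gene, by −1.11 ± 0.13 (adjusted p = 0.0762). The transcription factor genes POU3F2 and ISL1 differed by −0.83 ± 0.11 and −1.15 ± 0.16, and CHRDL1, a BMP antagonist gene, by −1.51 ± 0.21. With limma, 0 of 9686 genes passed, against 937 at an unadjusted p under 0.05 (484.3 by chance). In 1413 genes (14.6%, 10% by chance) all 3 KO-labelled lines lay above or all lay below all 3 wild-type lines. Without replicate 1 of A10, 5 genes passed: ETV5 (adjusted p = 0.0252), CHSY3 (0.0280), POU3F2 (0.0296), EDIL3 (0.0430) and ISL1 (0.0430), while CADPS2 did not (0.0616). With arrays in place of line means, the count was 75 with the line as a random block, 71 with the replicate 1 difference as a further term and 875 with the line ignored. On line means the count was 6 in replicates 2 and 3 alone and 0 in replicate 1 alone. It was 72 without the A10 line, 5 without N8 and 1 without B21.

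The CIC target list, genes that CIC is known to repress, rose in the KO-labelled lines. Its 10 measured members of 16 listed were all higher, by a mean of 0.49, from a list mean of 5.95 ± 0.08 to 6.45 ± 0.17 (SD, n = 3 lines). Adjusted over the list alone, 7 members passed, and 0 passed over all genes tested. They were the ETS transcription factor genes ETV5, ETV1 and ETV4 (0.84 ± 0.19) and the feedback inhibitors of MAP kinase signalling SPRY4 (0.57 ± 0.17), SPRY2 (0.31 ± 0.10), DUSP5 (0.68 ± 0.23) and DUSP4 (0.42 ± 0.15). GPR3 (0.20 ± 0.11), SHC3 (0.20 ± 0.10) and CCND1 (0.18 ± 0.11) did not pass. Camera with the preset correlation gave an adjusted p = 5.56e-10. With an estimated correlation the call was lost (adjusted p = 0.218), and fry gave an adjusted p = 0.0847. The list also differed between replicates, lower by −0.34 in replicate 1. The shift was 0.57 within replicate 1, 0.46 within replicates 2 and 3, and 0.55 without replicate 1 of A10.

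**Figure D1:**
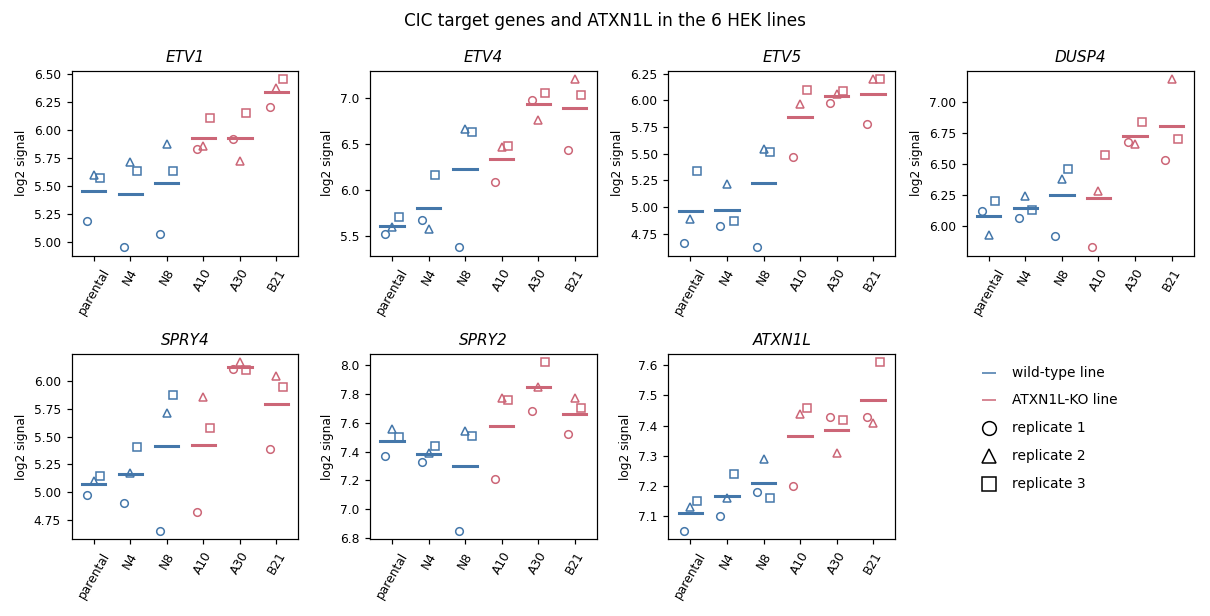
Each panel plots the log2 array value of ETV1, ETV4, ETV5, DUSP4, SPRY4, SPRY2 or ATXN1L for each of the 18 arrays, by line, with a symbol for each replicate number. ETV5 is near 5.05 in the wild-type lines and near 5.98 in the KO-labelled lines, with replicate 1 of A10 at 5.47.

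Of 25 listed extracellular matrix and mesenchymal genes only 6 had a probe set with a gene symbol, and all 6 passed the filter. These rose by a mean of 0.62, with 5 of 6 higher. FN1, which encodes fibronectin, rose by 1.31 ± 0.30, THBS1 (thrombospondin) by 1.05 ± 0.22 and CCN2 by 1.01 ± 0.26, adjusted over the list alone. TAGLN differed by 0.30 ± 0.18, and FBN1 and VIM by 0.08 ± 0.12 and −0.01 ± 0.10. The adjusted p was 0.00101, and with an estimated correlation the adjusted p was 0.455. CCN2 was also among the genes lower in replicate 1, and the list shift was 0.56 within replicate 1 and 0.66 within replicates 2 and 3. The wild-type line N8 differed from the parental cells by 0.45 on this list (adjusted p = 0.0603) and by 0.75 ± 0.23 in THBS1 (adjusted p = 0.0399). A10 differed by 0.43 from the mean of the wild-type lines, a reference that includes N8. List means were 7.27 in the parental cells, 7.37 in N4 and 7.72 in N8. They were 7.88 in A10, 8.03 in A30 and 8.325 in B21, all above those of the wild-type lines.

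Unfolded protein and amino acid stress genes, 9 measured of 17 listed, rose by a mean of 0.20, with 7 of 9 members higher. XBP1, a transcription factor of the unfolded protein response, rose by 0.45 ± 0.10, VLDLR by 0.76 ± 0.18 and SDF2L1 by 0.38 ± 0.11 adjusted over the list alone, while DDIT4 fell by 0.52 ± 0.10. Epithelial junction and keratin genes, 11 measured of 20 listed, rose by a mean of 0.20, with 9 of 11 higher and 0 passing adjusted over the list alone. CLDN1 differed by 0.61 ± 0.19, KRT19 by 0.70 ± 0.36, KRT18 by 0.41 ± 0.15 and PKP2 by 0.16 ± 0.10. Ribosomal protein genes, 17 measured of 28 listed, fell by a mean of 0.07, with 16 of 17 lower and 0 passing adjusted over the list alone. RPL35 differed by −0.16 ± 0.09, RPS9 by −0.13 ± 0.08 and RPL8 by −0.13 ± 0.09, and RPS6 was the exception at 0.16 ± 0.16. The adjusted p was 0.0358 for the stress genes, 0.0390 for the epithelial genes and 0.0390 for the ribosomal genes. With an estimated correlation the adjusted p was 0.414, 0.455 and 0.455. The epithelial list differed by 0.03 in A10, 0.20 in A30 and 0.37 in B21, and its KRT19 by −0.31, 1.18 and 1.24. Without B21 the shift was 0.12 (adjusted p = 0.140) for the epithelial list, 0.16 (0.0898) for the stress list and −0.07 (0.134) for the ribosomal list, so that none passed. Without the filter on dim probe sets the epithelial shift was 0.11 (0.206), and with neighbour centring the stress shift was 0.12 (0.143). The epithelial list did not pass within replicates 2 and 3, and the ribosomal list passed in neither part of the replicates. Leaving out replicate 1 of the parental cells ended all 3 calls (adjusted p = 0.0508 for each). The epithelial call also ended without N8 replicate 1 (0.0651), A10 replicate 2 (0.0661), A30 replicate 1 (0.0637) or A30 replicate 2 (0.0516), and without the parental line (0.131). The ribosomal call ended with quantile normalisation (−0.06, adjusted p = 0.0627), without parental replicate 2 (0.0598), N8 replicate 2 (0.0701), A10 replicate 2 (0.0514) or A30 replicate 1 (0.0637), and without the parental (0.131), N4 (0.0912) or A10 (0.172) line. The stress call ended without N8 (0.151).

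The other 13 lists did not pass. Members of the MAPK early-response list went both ways: MYC fell by 1.12 ± 0.26 and EGR1 by 0.61 ± 0.15, while ATF3 rose by 0.38 ± 0.12 and IER3 by 0.71 ± 0.22, adjusted over the list alone. The mean of its 12 members was −0.02 and the median 0.09, so mean and median differed in sign (adjusted p = 0.699). Of 11 Notch pathway genes, the ligand JAG1 rose by 0.41 ± 0.10, and HES4, JAG2 and the receptor NOTCH1 fell by 0.39 ± 0.10, 0.32 ± 0.09 and 0.32 ± 0.10, adjusted over the list alone (list adjusted p = 0.256). In the kidney developmental list, SIX2 differed by −0.24 ± 0.08 and EMX2 by −0.16 ± 0.09 (mean −0.12, adjusted p = 0.0673). In the neuronal list, MAP2 differed by −0.57 ± 0.20 (mean −0.15, adjusted p = 0.256). Mean differences were 0.04 for the G2 and mitosis genes (adjusted p = 0.262), 0.04 for the hypoxia genes (0.307) and 0.11 for the keratinocyte and fibroblast markers (0.530). They were −0.01 for the S-phase genes (0.699), −0.02 for the cholesterol synthesis genes (0.699), −0.03 for the oxidative phosphorylation genes (0.603) and −0.04 for the p53 targets (0.592). The interferon-stimulated genes had a mean of −0.06 and a median near 0 although camera's direction was up (0.977). The list of ATXN1, ATXN1L, CIC and co-repressors had a mean of 0.01 and a median of −0.02 (0.901).

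**Figure D2:**
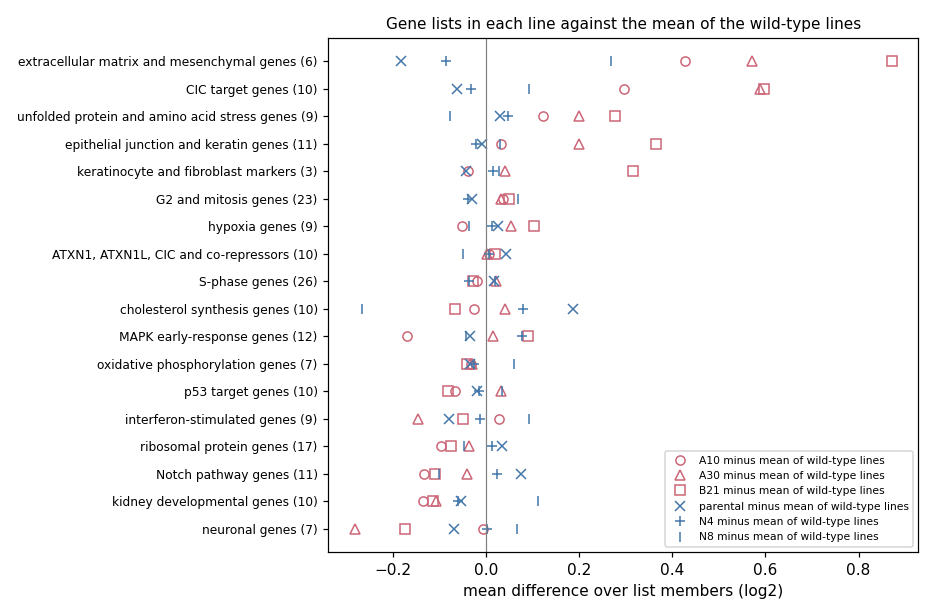
The mean difference of each gene list from the mean of the wild-type lines (log2) is plotted for each of the 6 lines, with the number of measured genes in brackets. The CIC target list was higher by 0.30 in A10, 0.59 in A30 and 0.60 in B21.

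Each KO-labelled line was also set against the wild-type lines. In A10, IRS2, an insulin receptor substrate gene, rose by 1.00 ± 0.06 (SE, adjusted p = 5.58e-08), MOSPD1 by 1.20 ± 0.12 and MIR4521 by 1.36 ± 0.23, while PLXDC2 fell by 2.61 ± 0.22, CAPN6 by 2.00 ± 0.17 and CHRDL1 by 1.61 ± 0.11. In A30, the matrix genes TNC (tenascin C) and FN1 rose by 1.80 ± 0.08 and 1.58 ± 0.20 and PAMR1 by 1.71 ± 0.10, while PLXDC2 fell by 2.85 ± 0.22, GALNT13 by 2.12 ± 0.21 and MYC by 1.70 ± 0.18. In B21, CPA4, TNC and ANKRD1 rose by 2.64 ± 0.21, 2.16 ± 0.08 and 2.15 ± 0.43, and EDN1, which encodes endothelin, by 1.96 ± 0.19. CAPN6 and CHRDL1 fell in B21 by 1.71 ± 0.17 and 1.51 ± 0.11. In all, 814 genes passed in A10 (372 up, 442 down), 2836 in A30 (1253 up, 1583 down) and 1551 in B21 (854 up, 697 down). With the replicate 1 difference as a term, the counts were 1335, 3457 and 2195, and in replicates 2 and 3 alone 1461, 2762 and 1671. With neighbour centring the count was 331 for A10 and 957 for B21. Without replicate 1 of A10 the A10 count was 1142. Without replicate 2 or replicate 3 of A10 it was 327 or 329, and without replicate 2 or replicate 3 of B21 the B21 count was 863 or 824.

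The CIC target list passed in A10, A30 and B21 alone (adjusted p = 0.0150, 0.00393 and 0.000216). With an estimated correlation the adjusted p was 0.698, 0.502 and 0.231. In B21 the matrix list differed by 0.87 (0.00184), the epithelial list by 0.37 (0.000711) and the stress list by 0.28 (0.0410). With an estimated correlation these adjusted p values were 0.0693, 0.156 and 0.231. In A10 the ribosomal list differed by −0.10 (0.0150, and 0.342 with an estimated correlation).

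Of the genes called in single lines, 147 passed in all 3 KO-labelled lines with the same sign, 72 up and 75 down. ETV5 was the only one of the 10 CIC targets among them. TNC rose in A10, A30 and B21 by 0.40 ± 0.08, 1.80 ± 0.08 and 2.16 ± 0.08. CHRDL1, CAPN6, PLXDC2, GALNT13 and MYC fell in each line, MYC by 0.95 ± 0.18, 1.70 ± 0.18 and 0.70 ± 0.18. Of these genes CAPN6, CHRDL1 and MYC also differed between wild-type lines: against the parental cells CAPN6 differed by 0.99 ± 0.20 in N4 and 2.45 ± 0.20 in N8, CHRDL1 by 0.95 ± 0.13 in N8 and MYC by −0.72 ± 0.22 in N8. The 3 contrasts share their reference. With a different wild-type line for each KO-labelled line the count was 42 to 66 over the 6 pairings. Lists drawn independently in each line would share 9.44 genes, but other splits of the 6 lines gave up to 282, with parental, N4 and A10 set against N8, A30 and B21. With the replicate 1 difference as a term 276 genes were shared, and 288 in replicates 2 and 3 alone. With each line centred on its neighbouring genes the count was 64, with 18 up and 46 down. With a 1.5-fold minimum it was 20, with 3 up and 17 down, so the even balance of rises and falls did not hold. Shared genes were 242 without replicate 1 of A10, 72 and 65 without replicates 2 and 3 of A10, and 85 and 90 without replicates 2 and 3 of B21.

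The CRISPR control lines were set against the parental cells. In N4, GREM1, a BMP antagonist gene, rose by 0.92 ± 0.15 (SE, adjusted p = 0.00938) and CAPN6 by 0.99 ± 0.20, while PTCHD1 fell by 1.14 ± 0.14 and the non-coding RNA gene FENDRR by 1.09 ± 0.09. In N8, CAPN6, ANKRD1 and the chemokine gene CCL2 rose by 2.45 ± 0.20, 1.91 ± 0.52 and 1.82 ± 0.31, and CA2, a carbonic anhydrase gene, by 1.58 ± 0.14. IGFBPL1, PCDH9 and SFRP2, a Wnt antagonist gene, fell in N8 by 1.82 ± 0.18, 1.47 ± 0.14 and 1.39 ± 0.09. In all, 53 genes passed in N4 (20 up, 33 down) and 1424 in N8 (743 up, 681 down). These counts have the parental cells alone as reference, unlike the counts given above for the KO-labelled lines. Against the parental cells alone, 635 genes passed in A10, 2431 in A30 and 1229 in B21, so N8 exceeded A10 and B21 on that reference. With the replicate 1 difference as a term, the counts were 171 in N4 and 2118 in N8, and in replicates 2 and 3 alone 56 and 1523. With neighbour centring they were 18 and 503. Without 1 array the N4 count ran from 9 to 116, as 13, 30 and 15 without replicates 1, 2 and 3 of the parental cells, 35, 9 and 18 without those of N4 and 116 without replicate 1 of A10. Without replicate 3 of the parental cells the N8 count was 876.

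Lines of one genotype differed from each other. Among the KO-labelled lines, the ranges of line means were 2.50 for LOC100507412, 2.22 for ENPEP, 2.21 for CPA4, 2.13 for TCEAL7 and 1.97 for CLGN. Among the wild-type lines they were 2.60 for EPHA7, an ephrin receptor gene, 2.45 for CAPN6, 2.31 for CCL2, 2.19 for ANKRD1 and 2.00 for NAP1L3. The F test passed for 2503 genes (25.8%) among the KO-labelled lines and 1561 (16.1%) among the wild-type lines, and for 3326 and 2404 with the replicate 1 difference as a term. With neighbour centring it passed for 1274 and 540.

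Neighbouring genes shifted together in single lines. In A30, all 40 tested genes from LINC01061 to SMAD1 were lower than in the parental cells, with a median of −0.61 (log2). The 40 genes from ATOH1 to USP53 had a median of −0.60, and those from NAAA to GPRIN3 −0.58. In B21, 37 of 40 genes from MAB21L1 to RB1 were lower, with a median of −0.48. In N8, the genes from TLN1 to C9orf40 had a median of −0.39 and those from C20orf96 to PRNP 0.32. In A10 the genes from LRSAM1 to ASB6 had a median of −0.31, and in N4 those from GTPBP6 to MIR23C 0.22. Of 231 windows of 40 genes, 39 in N4, 51 in N8, 41 in A10, 36 in A30 and 33 in B21 lay beyond the 95th percentile of the highest value in 1000 shuffled orders.

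**Figure D3:**
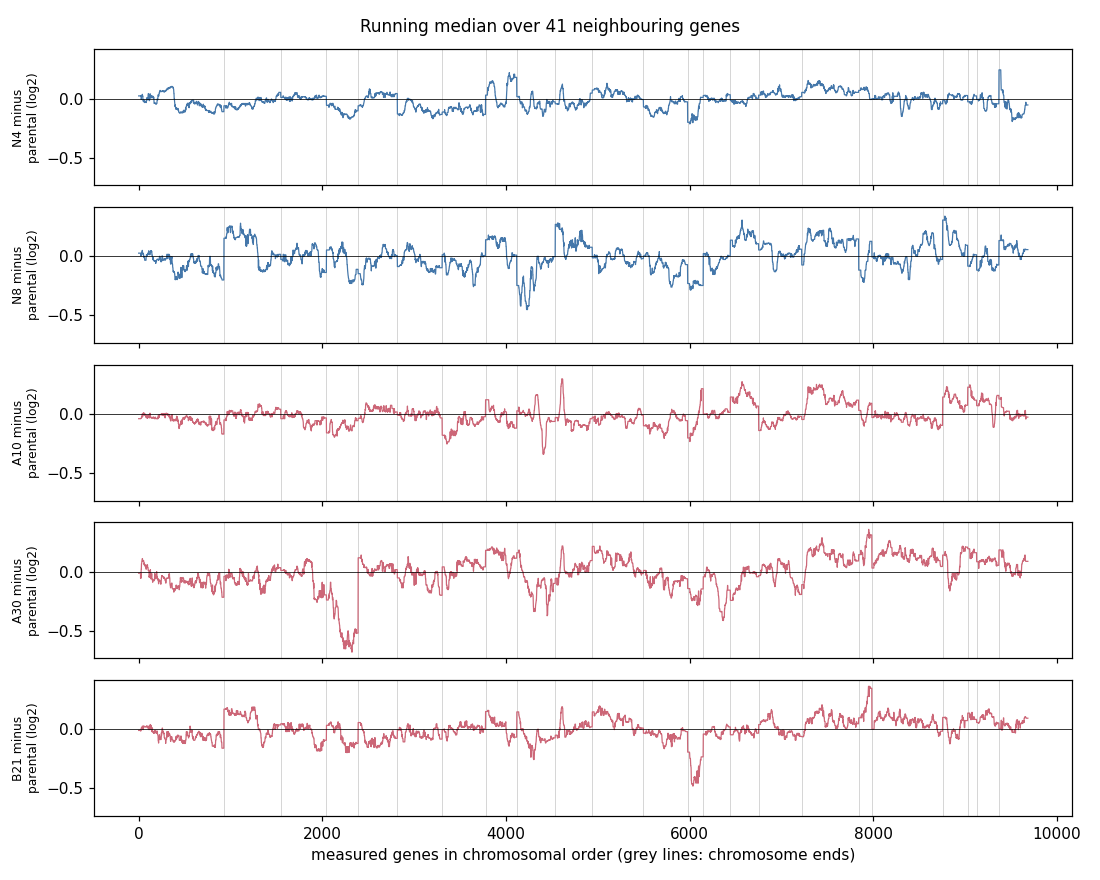
The running median over 41 neighbouring genes of each line minus the parental cells (log2) is drawn along the gene order for N4, N8, A10, A30 and B21. A30 has the deepest run, with windows of 40 genes at −0.61, −0.60 and −0.58.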

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

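The tests against replicate 1, all those on runs of neighbouring genes and all on the ATXN1L signal were chosen only after the results were seen, and those on other splits of the lines and arrays, and on the spread between clones, before.

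Of 131 genes named here or taken by the naming rule, 57 differed between the KO-labelled lines in their change against the wild-type lines by limma's F test (adjusted p from 2.13e-09 to 0.0485). The rule takes genes with large changes or ranges in single lines, so this share says nothing of genes in general, where the same test passed for 25.8%. The range of the 3 changes (log2) was 2.50 for LOC100507412, 2.22 for ENPEP, 2.21 for CPA4, 2.13 for TCEAL7, 1.97 for CLGN, 1.95 for PURPL, 1.92 for CCL2, 1.85 for PAMR1, 1.81 for MYOF, 1.76 for TNC, 1.75 for EDN1, 1.68 for PLXDC2 and 1.55 for KRT19. It was 1.47 for DPYD, 1.36 for FN1, 1.33 for IFIH1, 1.27 for KRABD1, 1.20 for PCDH9, 1.20 for RYR2, 1.08 for MOSPD1, 1.04 for LUM, 1.00 for GALNT13, 0.99 for MYC, 0.98 for DUSP5 and 0.97 for IER3. Smaller ranges were 0.83 for CLDN1, 0.80 for VLDLR, 0.78 for FENDRR, 0.76 for CA2, 0.74 for MAP2, 0.73 for NDRG1, 0.71 for HDX, 0.69 for IRS2, 0.67 for IGFBPL1, 0.63 for GREM1, 0.61 for DTX3, 0.58 for DUSP4, 0.57 for HOXD11, 0.56 for SFN, 0.54 for GDF15, 0.54 for HMGCS1, 0.53 for EDIL3 and 0.50 for ADM. The smallest were 0.44 for RIBC2, 0.41 for MAP3K15, 0.41 for CCND1, 0.40 for UCHL1, 0.38 for IDI1, 0.35 for ATF3, 0.33 for HES4, 0.32 for BNIP3L, 0.32 for SFRP2, 0.31 for MSMO1, 0.31 for PKP2, 0.27 for DHCR7, 0.23 for VIM and 0.23 for CDC45. Among them are DUSP4, DUSP5 and CCND1 of the CIC target list and FN1 of the matrix list. Probe sets with no gene name, which the report's comparisons do not use, were tested as well: of 14000, 69 passed in all 3 KO-labelled lines with the same sign, 40 up and 29 down. The 3 contrasts share their reference, and another split of the lines gave 146, so these counts do not set the KO-labelled lines apart.

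The CIC target list was higher in the KO-labelled lines by 0.49. A difference between replicates that is equal in all lines cancels from this comparison, since every replicate number is present in each line. A shift confined to replicate 1 or to the later replicates is argued against, because it was 0.57 in replicate 1 alone, where it passed, and 0.46 in replicates 2 and 3 alone. Runs of neighbouring genes are argued against as its whole cause, because the shift was 0.52 once each line was centred on its neighbours. The spread between clones that would arise without the edit stays open. The highest of the other splits of the 6 lines, parental, N4 and A10 against N8, A30 and B21, gave 0.36 (camera adjusted p = 0.00780). Every other split has KO-labelled lines on both sides, so its shift holds part of any genotype difference and does not measure spread without the edit. The 10 splits are too few for a share under 0.05, and only 1, the real one, was as large as the real one. List means were 5.89 in the parental cells, 5.92 in N4 and 6.05 in N8. They were 6.25 in A10, 6.54 in A30 and 6.55 in B21, all above those of the wild-type lines. An effect of the ATXN1L edit on CIC target genes may account for the shift, but it cannot be told apart from clonal spread with 3 lines of each genotype.

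Runs of neighbouring genes were shifted together in single lines. Chance placement of changed genes is argued against, because the line with the fewest windows beyond the limit had 33 of 231. Copy number differing between lines may account for the runs, but any shift of a whole region would give what was tested: of 200 windows chosen on their bright genes in replicate 1, 86% had dim genes that shifted the same way in replicates 2 and 3, against 64.3% of the other windows. The spread of gene differences within the chosen windows was 1.10 times that in the others. A shift equal in all genes of a window leaves this spread unchanged, so it cannot show whether genes shifted alike. No DNA was measured, so copy number and regulation of whole regions cannot be told apart.

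The ATXN1L signal was higher in the KO-labelled lines by 0.25. A gain of the surrounding region is argued against, because the median difference of 40 neighbouring genes was −0.077 (quartiles −0.137 and −0.005) and 0 of them reached that of ATXN1L. A difference between replicates that is equal in all lines cancels here too. That the rise is confined to 1 part of the replicates is argued against by 0.24 ± 0.12 (SE) in replicate 1 and 0.25 ± 0.09 in replicates 2 and 3. A transcript that persists or is made at a higher rate in edited cells could account for the rise, but it was not tested, nor was an exchange of labels between lines.

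Other splits of the same lines or arrays were counted for each comparison. For the genotype comparison all 10 splits called 0 genes. At an unadjusted p under 0.05 the split of parental, N4 and A10 against N8, A30 and B21 gave 1168 genes, more than the 937 of the real one. For the gene lists 1 of 10 splits, the real one, reached 5, and the highest other gave 4. For the shared genes 3 of 10 reached the real 147, and the highest other, again parental, N4 and A10 against N8, A30 and B21, gave 282. With the sides exchanged, the real split gave 324 shared genes and that split 434. That 1 split, which exchanges A10 and N8, exceeded the labels on both counts, while the labels gave more lists and a larger CIC target shift (0.49 against 0.36). The splits were run only with replicate 1 of A10 included, an array nearer to N4 and the parental cells than to its own line. By limma's F test 2503 genes differed among the KO-labelled lines and 1561 among the wild-type lines, so the lines do differ beside the genotype. Whether the split that exchanges A10 and N8 exceeds the labels without replicate 1 of A10 was not tested. The other 8 splits gave 134 to 577 genes at an unadjusted p under 0.05. In each case 10 splits are too few for a share under 0.05.

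Among 100 splits of the arrays, only the real one gave as many genes for A10 (814, highest other 42), A30 (2836, highest other 906), B21 (1551, highest other 976), the spread among KO-labelled lines (2503, highest other 1119) and the spread among wild-type lines (1561, highest other 1159). These splits exchange arrays between lines, so they show that arrays of a line resemble each other, and nothing about genotype. For N4 the real split gave 53 and the highest other 1, and for N8 they gave 1424 and 1. In both, 1 of 10 splits reached the real count, and 10 are too few for a share under 0.05.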

How the results depend on the processing

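The tests within replicate 1 or replicates 2 and 3, with the replicate 1 difference as a term, with neighbour centring and with N8 left out of the reference were chosen after seeing the data; the others were planned. For each value below the cause was not tested, except that a looser threshold calls more genes and a stricter one fewer by construction. Over 39 alternatives the CIC target and matrix lists passed in all, with shifts of 0.41 to 0.59 and 0.50 to 0.76, the stress list in 35, the epithelial list in 29 and the ribosomal list in 26, all by camera at the preset correlation. With an estimated correlation none of these lists passed (adjusted p = 0.218 for the CIC targets and 0.455 for the matrix list), nor with fry (0.0847 and 0.293). ETV5 passed in 11 of 38 (adjusted p 0.000264 to 0.336) and ATXN1L in 1 of 39 (0.00555 to 0.815). Apart from leaving out an array or line, 513 results for single genes and lists kept direction and side of the threshold. Of the rest, 44 came to pass, 8 no longer passed, 10 moved and 1, the MAPK list, reversed in the sign of its mean. That mean was 0.14 in replicate 1 alone, where the list passed (adjusted p = 0.0342). In the main fit it was −0.02, but camera's direction was up (adjusted p = 0.699). Of the comparison counts, 114 stayed within 1.5 times and 49 moved. On leaving out an array or line, 873 results for single genes and lists were the same, 33 came to pass, 19 no longer passed and 11 moved, and 163 comparison counts stayed within 1.5 times and 29 moved.

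The genotype comparison called 7 genes at an adjusted p under 0.1, 75 with the line as a random block, 875 with arrays taken as independent, 43 with a replicate-number block, 71 with the replicate 1 term and 6 in replicates 2 and 3, where 3 lists passed. In replicate 1 alone it called 0 genes and 7 lists passed, 6 up and 1 down. Without the filter on dim probe sets A10 had 510 genes, the shared genes were 92 and N4 had 26. With all probe sets A30 had 4792 and N8 2168. At an adjusted p under 0.1 A10 had 1277, the shared genes were 261, N4 had 143 and the spread among wild-type lines 2347. With a 1.5-fold minimum the counts were 81 for A10, 320 for A30, 195 for B21, 20 shared, 12 for N4, 188 for N8, 512 among KO-labelled and 265 among wild-type lines. With the replicate block they were 1379 for A10, 287 shared, 168 for N4, 2149 for N8 and 2427 among wild-type lines, and with the replicate 1 term 1335 for A10, 276 shared, 171 for N4 and 2404 among wild-type lines. The labels do not say that a number marks a shared day, but with the line means removed 15 of 18 arrays correlated best, on average, with arrays of their own number, a hint from the data. Pairs of the same number then correlated at 0.165 to 0.514 for replicate 1, 0.090 to 0.381 for replicate 2 and −0.004 to 0.252 for replicate 3, where 10 of 15 were over 0.1. Pairs of replicate 2 with replicate 3 correlated at −0.257 to 0.288, with 19 of 30 over 0.1, so these numbers are not clearly separate. Replicates 2 and 3 alone gave 1461 for A10 and 288 shared. Neighbour centring gave 331 for A10, 957 for B21, 64 shared, 18 for N4, 503 for N8, 1274 among KO-labelled and 540 among wild-type lines. Shared genes were 225 with parental and N4 as reference and 42, 52, 51, 51, 66 and 55 in the 6 pairings.

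Without 1 array the counts ran from 0 to 5 for genotype, 2 to 5 for lists, 327 to 1142 for A10, 2151 to 3078 for A30, 824 to 1816 for B21, 65 to 242 shared, 9 to 116 for N4, 876 to 1688 for N8, 2056 to 2727 among KO-labelled and 1059 to 1861 among wild-type lines. The genotype count was 5 without A10 replicate 1, 3 without B21 replicate 3, 2 without parental replicate 2, and 1 without N8 replicate 2 or 3. The list count was 2 without parental replicate 1 and 3 without A10 replicate 2 or A30 replicate 1. Without 1 line the genotype count ran from 0 to 72, at 72 without A10, 5 without N8 and 1 without B21, and the list count from 2, without B21, to 7. Signal over background limits dim genes: of the CIC targets, DUSP6 (4.73 and 5.03) and MAFF (5.33 and 5.53 in wild-type and KO-labelled lines) lay below the filter. Several genes named were tested with 1 genotype below the filter value of 5.6. Among them were the wild-type means of ETV5 (5.05), ETV1 (5.47), SPRY4 (5.21), DUSP5 (5.03), GPR3 (5.49) and SHC3 (5.50). The KO-labelled means of CHSY3 (4.86), ISL1 (5.34), CHRDL1 (5.35), CADPS2 (5.46), PLXDC2 (5.51), CAPN6 (5.24) and GALNT13 (5.02) also lay below it. Background was not measured there, so how far the sizes of these differences depend on it is not known.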

Other observations

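The test of the gene lists between replicates and the comparison of the A10 arrays were chosen only after the differences were seen.

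Cholesterol synthesis genes were lower in the CRISPR control line N8 than in the parental cells, with all 10 measured members lower by a mean of −0.45. INSIG1, a sterol-sensing regulator, fell by 0.96, HMGCS1, an early enzyme of the pathway, by 0.85, and MSMO1, SQLE and DHCR7 by 0.51, 0.50 and 0.50. The list's adjusted p was 1.96e-06, and 0.0753 with an estimated correlation, where it did not pass. N8 was 1 of the 3 wild-type lines, and the list's difference between the genotypes, −0.02, rested on it: without N8 it was −0.15 and passed (adjusted p = 0.0251). Without the parental cells or N4 it was 0.08 or 0.02, and did not pass.

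In replicate 1 against replicates 2 and 3, the CIC target list was lower by −0.34 (adjusted p = 6e-05) and the stress list by −0.13 (0.0399), while the p53 targets were higher by 0.16 (0.00414). The G2 and mitosis genes were lower by −0.08 (0.00508). With an estimated correlation the adjusted p was 0.194 for the CIC targets, the stress genes and the G2 and mitosis genes and 0.266 for the p53 targets. MT1X, a metallothionein gene, and DUSP1, a phosphatase gene, were lower in replicate 1 by −0.55 ± 0.08 (SE) and −0.64 ± 0.07.

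In replicate 1 of A10, CHSY3 was at 5.80, against 4.54 and 4.69 in the other A10 arrays and 5.98 in the wild-type lines, and ISL1 was at 6.09, against 5.21 and 5.13, with 6.49 in the wild-type lines. DPYD was at 6.06, against 4.13 and 4.70. CAPN6 was at 4.79, against 5.28 and 5.04, with 7.04 in the wild-type lines. Of the 32 genes that differed by at least 1 (log2) in the other A10 arrays, 12 reached under 25% of that difference in this array and 4 reached at least 75%.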
